A study of Mus musculus with 6 samples.

How the data were processed

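RNA from 6 heart samples of male C57BL6N mice was measured on 1-colour Agilent expression arrays, 1 array per sample. Per the labels' protocols, mice received an adeno-associated virus of serotype 9 by the intravenous route, either a control vector (control group) or a vector for miR-212 and miR-132 (microRNA group), and then doxorubicin at 5 mg/kg from the next day, repeated weekly on 4 further occasions, with the mice killed 1 week after the last dose. An amount of 250 ng of total RNA per sample was amplified to cRNA and coupled to an Alexa Fluor dye, per the labels' protocols.

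The authors deposited 1 scanner file per array. Its spot intensity values came from Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and spatially detrended without multiplicative detrending, and was not normalized between arrays. The genome build behind the probe design is not given in the sources used here. The authors also deposited a value table of 245 probes. Its scale and centring were not stated, so each column was set against the scanner signal of the same array. The signal values of this table, as deposited by the authors, had been put on a linear scale with 1 factor per array, where a value of 1 stood for a scanner signal of 2449 to 2699. The column medians were 0.335, 0.353 and 0.333 for control replicates 1 to 3 and 0.321, 0.315 and 0.300 for the microRNA replicates. How the authors chose that factor stays unknown. Of the 245 probes, 193 followed the scanner signal of the probe they name within 0.3 log2 units, and 52 did not. For 22 of those 52 the closest profile on the array belonged to a probe with the same transcript accession. Values of the table were used by gene name for the 193 only.

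Each array held 157716 spots other than controls, 4 for each of 39429 probes. Between 2.32% and 2.71% of these spots were left out as non-uniform or population outliers, and 0 were saturated. Between 63.0% and 67.3% of probes were well above background, and the 75th percentile of the processed signal was 1410 to 1590. The main values were log2 of the processed signal minus the array's 75th percentile, averaged over the spots of a probe. A probe entered the test when most of its spots were well above background on every array of at least 1 group. These were 24945 probes. They stood for 20266 genes, each represented by its brightest probe. Names came from RefSeq accessions without version through a gene table of assembly GRCm38.p6. A symbol was found for 28330 probes and not for 11099, which kept the name in the file. Of the genes tested, 14941 had a symbol. Levels of different probes were not compared with each other.

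The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all 20266 genes and a call at an adjusted p under 0.05. An exact permutation of 3 arrays against 3 cannot go below p = 0.1, so no single gene was tested that way. For 37 gene lists of pathways, reported microRNA targets and cell type markers, limma's camera was run with a preset inter-gene correlation of 0.01 and adjusted over the 35 lists with at least 5 measured members. The epicardium and mesothelium list and the lung epithelium list had 3 measured members each and were not tested. Beside camera stand the same test with an estimated correlation and fry. The groups, lists, tests and alternatives were fixed before the data were examined, except those that follow, which were chosen after seeing the data. They are the median over spots, the single-spot floor of a bound, the fit without replicate 2 of both groups, the estimated correlation and fry under blocks, with array weights or with arrays left out, and the tests of the slide, the fibroblast share, other probes and the fatty acid oxidation list in the closing section. Where no array of a group was above background, a fold is a lower bound, computed with the dim group at the higher of its own signal and the lowest signal, as a mean over spots, of a probe well above background on that array.

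The genes named are, in each direction, the 12 with the smallest unadjusted p among those at least 1.5-fold apart, with no overlap of the groups and a symbol other than a clone or predicted name, because fewer than 12 passed the test. Added to them are the 4 members with the smallest p of each called list and of the list of reported targets, and Fitm2, Foxo3, Rasa1, Nppa, Nppb, Myh6 and Myh7 in every case. For 2 of these list members the values are not reported here. Mir132 and Mir212 were on this list too, but 0 probes carried their names, so the vector's product was not checked. A planned test of genes with miR-132 or miR-212 seed sites needs untranslated region sequences and was not run.

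The labels number the samples 1 to 3 in both groups. The deviations of same-numbered arrays from their group means correlated across genes at 0.253, 0.498 and 0.354 for numbers 1, 2 and 3. Each is above 0.1, the value used here to take numbers as pairs. Deviations from a group mean cancel out within the group, so a profile shared by replicate 2 also raises the correlations of numbers 1 and 3. For 2 of the 3 control arrays the microRNA array of the same number correlated best. Pairing was thus not established for each number, and no label says what a number stands for. The main fit does not use the numbers. The fit with the number as a block is an alternative, given for the called lists and where it changes a call or moves a count by over 1.5 times. Arrays that share a scan time were taken to lie on the same slide, which gives 3 slides, and no slide identifier was read. Slide 1 held replicate 1 of both groups, slide 2 held control replicates 2 and 3 with microRNA replicate 2, and slide 3 held microRNA replicate 3 alone. No label says that the samples came from separate animals in so many words, so p-values measure the spread between these samples.

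The fit and the list test were tried on simulated data for the comparison of microRNA with control, drawn for all 20266 genes from the real means and residual SDs, with 200 genes changed. Of 67 genes changed 1.5-fold, 10.4% were called. For 67 genes changed 2-fold the share was 47.8%, and for 66 genes changed 4-fold it was 80.3%. Among the unchanged genes 8 were called. A list of 30 genes lowered 1.2-fold was called at an adjusted p of 3.54e-10 and an unshifted list of 30 was not, at an adjusted p of 0.427. The simulated noise was independent between genes, which the real noise is not. The alternatives cover background correction, scaling, the filter on dim probes, the choice of probe, the variance model, array weights, blocks for replicate number and slide, the threshold, the set test and each array left out in turn. The number of arrays limits the precision of every value.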

Results

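Hearts of doxorubicin-treated mice were profiled after gene transfer with AAV9, a cardiotropic viral vector that carried either a control construct (control samples) or miR-212 and miR-132 (microRNA samples), which share a seed. Doxorubicin is an anthracycline whose use is limited by damage to the heart, and the series title frames the question as which genes miR-212 and miR-132 target in that setting. Each group held 3 samples on 1 array each. No sample without doxorubicin is part of the comparison. Signals are log2 values relative to the 75th percentile of the array, differences are microRNA minus control, and the errors are limma standard errors from 3 arrays against 3.

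Among the genes with the clearest separation, Dsg1c, a desmosomal cadherin, was higher in microRNA samples by 1.56 ± 0.16 (SE) log2 units, and the co-chaperone Dnajb8 by 1.69 ± 0.22. Vmn1r197, a vomeronasal receptor, was higher by 1.92 ± 0.22. Rxfp3, a receptor for relaxin-3, was 2.84-fold higher, and Oxct2b, a ketone body enzyme, was higher by 1.09 ± 0.19 log2 units. Cyp1a1, a cytochrome P450 that metabolises foreign compounds, was lower, with a log2 difference of -1.71 ± 0.38. Arntl, which encodes the core clock factor BMAL1, differed by -0.77 ± 0.18, Aqp4, a water channel, by -0.76 ± 0.24 and the integrin subunit Itgb3 by -0.60 ± 0.17.

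The other genes named in the higher direction were Agmat (0.86), Arhgap32 (0.89), Cep112 (0.63) and Fam166b (0.77), together with 3 whose signal was not well above background on any control array. Those were Bcl2l14, at least 2.26-fold higher, Ascl3, at least 1.47-fold higher, and Dnaic2, at least 1.46-fold higher. With the lowest single spot above background as the floor, these bounds were 1.88-fold, 1.13-fold and 1.18-fold. In the lower direction they were Celsr2 (-0.60), Btnl9 (-0.70), Tmeff2 (-0.71), Gatad2b (-0.68), Olfr224 (-0.85), Adamts4 (-1.25), Kcnq5 (-0.62) and Slc24a4 (-1.04). Without control replicate 2 the difference of Gatad2b was -0.44. Olfr224, Adamts4 and Kcnq5 were above background on 2 of the 3 microRNA arrays and Slc24a4 on 1. Where these genes had another probe above background on all 6 arrays, the probes did not always move alike. A further Rxfp3 probe differed by 0.05 and a further Celsr2 probe by 0.01, while a further Aqp4 probe differed by -0.53. The further Oxct2b probe, above background on 1 array, differed by 0.09.

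**Figure D1:**
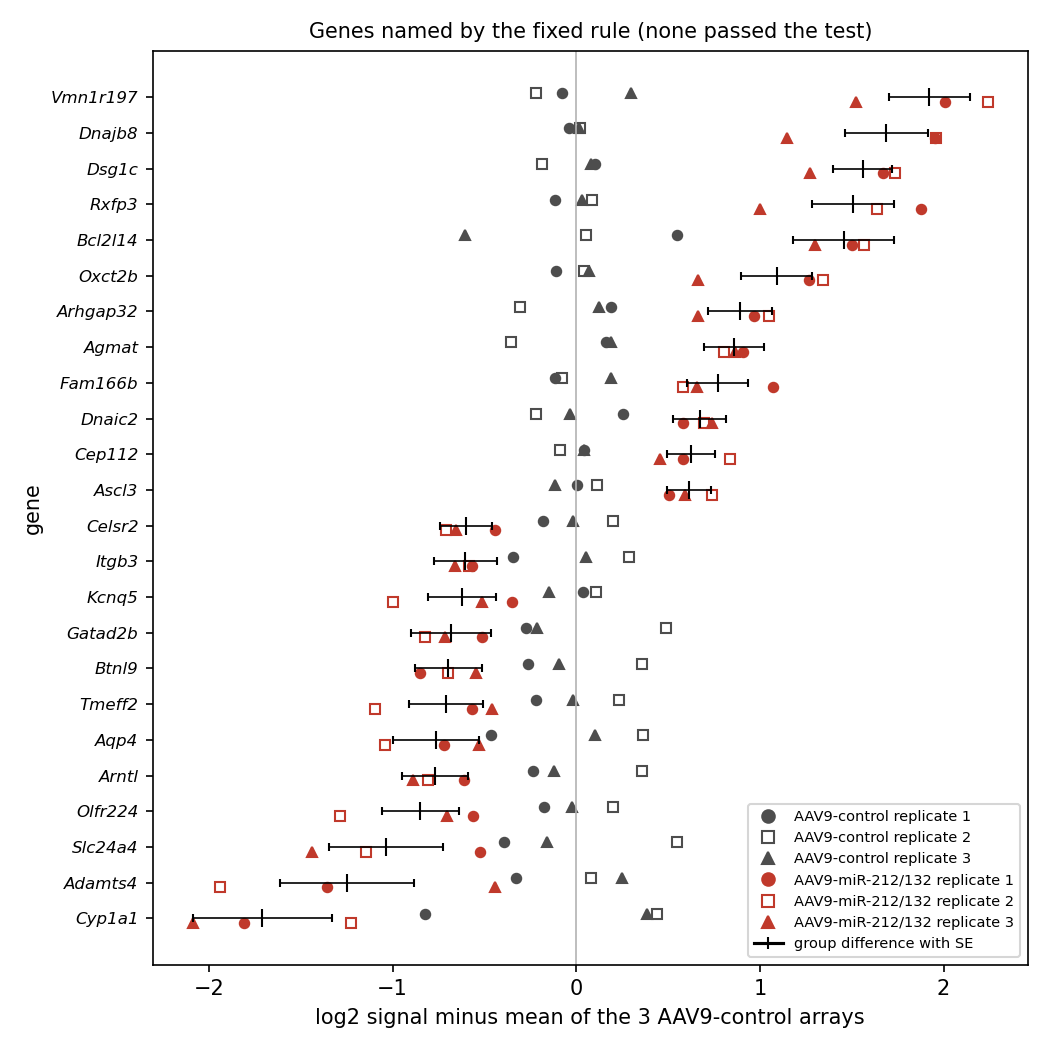
Log2 signal of 24 genes on each array, minus the mean of the control arrays, with the group difference and its standard error as a black bar. Each microRNA point of Dsg1c, Dnajb8 and Vmn1r197 lies above the control points and each of Cyp1a1 and Arntl below them; no gene passed the test, and the control points of Bcl2l14, Ascl3 and Dnaic2 are not above background.

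None of these genes passed the test. Of 20266 genes, 0 had a limma adjusted p under 0.05, and the smallest adjusted p was 0.498, shared by Dsg1c and Vmn1r197. At an unadjusted p under 0.05 there were 515 genes, 276 higher and 239 lower, where chance gives 1013. The groups did not overlap in 1618 genes, or 7.98%, where chance gives 10% for 3 arrays against 3, and 84 of these were at least 1.5-fold higher and 50 at least 1.5-fold lower. With the replicate number as a block 0 genes passed and 852 had an unadjusted p under 0.05, and with slide as a block 0 and 878. With limma's array weights, which put 5.72 and 5.89 on control replicate 3 and microRNA replicate 1, 507 genes were called, 243 higher and 264 lower. The other arrays had weights of 0.249 to 0.629. That fit thus rests mostly on a single array per group, and its count does not measure the spread between samples.

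Among the 28 measured genes of the reported targets of miR-212 and miR-132, 12 were higher and 16 lower. No shift of the list as a whole was detected, with a median of -0.04 and a camera adjusted p of 0.629. Fitm2, which encodes a lipid droplet protein of the endoplasmic reticulum, was lower on each microRNA array than on any control array, with a difference of -0.38 ± 0.15 (unadjusted p = 0.0369 in the limma fit). Without control replicate 2 the Fitm2 difference was -0.23, with an unadjusted limma p of 0.0878. Arhgap32, a GTPase-activating protein, lay the other way at 0.89 ± 0.18. The groups did not overlap in 2 of the 28 targets, Fitm2 and Arhgap32, where the share over all genes was 7.98%. The absence of overlap is thus no mark of the targets. Spred1 differed by 0.25 ± 0.12 and Map3k3 by -0.34 ± 0.20, and the Ras regulator Rasa1 and the transcription factor Foxo3 by 0.07 each, with standard errors of 0.17 and 0.20. Map3k3 differed by -0.15 without control replicate 2 and by -0.20 without microRNA replicate 1. Foxo3 ran from -0.14 to 0.18 and Rasa1 from -0.0403 to 0.23 with an array left out. Foxo3 was above background on 2 of the 3 control arrays. Over all genes 0 of the 28 passed, and adjusted over the list alone 1 did, Arhgap32, with an adjusted p of 0.0389.

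The markers of cardiac load showed no separation. Nppa, atrial natriuretic peptide, differed by 0.20 ± 0.18, and the myosin heavy chains Myh6 and Myh7 by -0.12 ± 0.14 and 0.48 ± 0.58. Nppb, brain natriuretic peptide, differed by 1.56 ± 1.07, and that value rested on control replicate 2, at 2.05, where the other 5 arrays lay between 6.01 and 6.84. Without that array the Nppb difference was 0.17. With an array left out, Nppa ran from 0.0024 to 0.31, Myh6 from -0.21 to 0.0181 and Myh7 from -0.0476 to 0.96. The list of hypertrophy and fetal genes had 13 of 20 members higher, 7 lower and 0 that passed, with a camera adjusted p of 0.542.

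Genes of fatty acid oxidation were lower as a list in microRNA samples, 29 of 31 measured members lower and 2 higher, with a median of -0.12, a call by camera with its preset correlation that did not hold with an estimated correlation (adjusted p = 0.951), with fry (0.993) or with slide as a block (0.104). The members with the smallest p were the mitochondrial uncoupling proteins Ucp3 (-0.93 ± 0.36) and Ucp2 (-0.80 ± 0.34), Pdk4 (-1.63 ± 0.74), a kinase that inhibits pyruvate dehydrogenase, and Cpt1a (-0.34 ± 0.19), which controls entry of fatty acids into mitochondria. Erythroid genes were lower in 8 of 8 members with a median of -0.21, among them the carbonic anhydrase Car2 (-0.26 ± 0.10), the anion exchanger Slc4a1 (-0.52 ± 0.23) and the globin Hbb-bt (-0.19 ± 0.12). Glucocorticoid response genes were lower in 20 of 20 members with a median of -0.29, including Angptl4 (-1.33 ± 0.96), Zbtb16 (-0.88 ± 0.84) and Mt2 (-0.80 ± 0.78) next to Pdk4, which both lists hold. Interferon response genes were higher in 24 of 32 members and lower in 8, with a median of 0.17. Irf1 (0.48 ± 0.17) and Ifit2 (0.60 ± 0.28) were higher and the GTPase Iigp1 was lower (-0.67 ± 0.30).

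Several of these members rested in part on control replicate 2. Without it the differences were -0.54 for Ucp3, -0.38 for Ucp2, -0.77 for Pdk4, -0.22 for Cpt1a, -0.29 for Iigp1 and 0.36 for Ifit2. Zbtb16 and Mt2 turned to 0.14 each without this array, so their lower values were those of 1 array. Ifit2 also differed by 0.36 without microRNA replicate 2, and Slc4a1 by -0.25. Angptl4 ran from -2.21 without control replicate 1 to -0.49 without microRNA replicate 1.

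These 4 of the 35 lists were called by camera with the preset correlation, with adjusted p of 4.33e-05 for fatty acid oxidation, 0.00058 for erythroid, 0.00559 for interferon and 0.0164 for glucocorticoid genes. The median estimated correlation over the lists was 0.175, above the preset 0.01, so these p-values can be too small. When the arrays were regrouped 3 against 3, the other splits that part all same-numbered pairs called 7, 8 and 6 lists by camera. Each of these counts is above the 4 of the real grouping. No call held with an estimated correlation (adjusted p = 0.951 with an estimated correlation for each of the 4 lists), and fry called 0 lists, with an adjusted p of 0.993 for each of the 4. None of the members of the 4 lists passed the gene test, over all genes or adjusted over the list alone (0 in each list). With the replicate number as a block, 6 lists were called, the same 4 with lipid droplet genes (lower, median -0.07, adjusted p = 0.0373) and inflammatory cytokine genes (higher, median 0.17, adjusted p = 0.0098) added. Under it the camera adjusted p was 1.6e-06 for fatty acid oxidation, 0.00065 for erythroid, 0.0021 for interferon and 1.24e-05 for glucocorticoid genes. With this block no call held with an estimated correlation (adjusted p = 0.919 with an estimated correlation for both added lists) or fry (0.717 for both). Without control replicate 2 the inflammatory list had a median of 0.0348 (adjusted p = 0.89), and without microRNA replicate 3 the lipid droplet list had -0.0373 (adjusted p = 0.128). The lists of oxidative phosphorylation (26 of 35 lower, adjusted p = 0.122) and cardiomyocyte genes (14 of 16 lower, adjusted p = 0.122) were not called, nor were those of p53 and DNA damage response, apoptosis regulators, extracellular matrix, macrophages, endothelial cells or fibroblasts, with adjusted p of 0.629, 0.923, 0.376, 0.629, 0.563 and 0.777. In 8 of the 35 lists the median, the mean and the test differ in sign, 0 of them called, and among those just named these are the endothelial list (median 0.0091, tested as lower) and the apoptosis list (median -0.02, tested as higher).

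Each of the 4 calls ended with slide as a block, where the medians were -0.02 for fatty acid oxidation, -0.15 for erythroid, 0.09 for interferon and 0.0033 for glucocorticoid genes, with adjusted p of 0.104, 0.0593, 0.407 and 0.407. Within slide 1 the medians were -0.04, -0.06, -0.02 and 0.34 in that order. Within slide 2, with microRNA replicate 2 set against the mean of control replicates 2 and 3, they were -0.01, -0.22, 0.18 and -0.25. Left-out arrays moved calls too. Without control replicate 2 the glucocorticoid list turned higher (median 0.25, adjusted p = 0.014, and adjusted p = 0.812 with an estimated correlation) and the interferon list had a median of -0.04 (adjusted p = 0.258). Without microRNA replicate 3 the call was lost for fatty acid oxidation (-0.07, adjusted p = 0.0677), interferon (0.10, 0.202) and glucocorticoid genes (-0.09, 0.234), and without microRNA replicate 1 for glucocorticoid genes (-0.27, 0.18). Over all alternatives the adjusted p ran from 1.37e-09 to 0.993 for fatty acid oxidation, 5.95e-05 to 0.993 for erythroid, 4.96e-07 to 0.993 for interferon and 2.82e-06 to 0.993 for glucocorticoid genes.

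**Figure D2:**
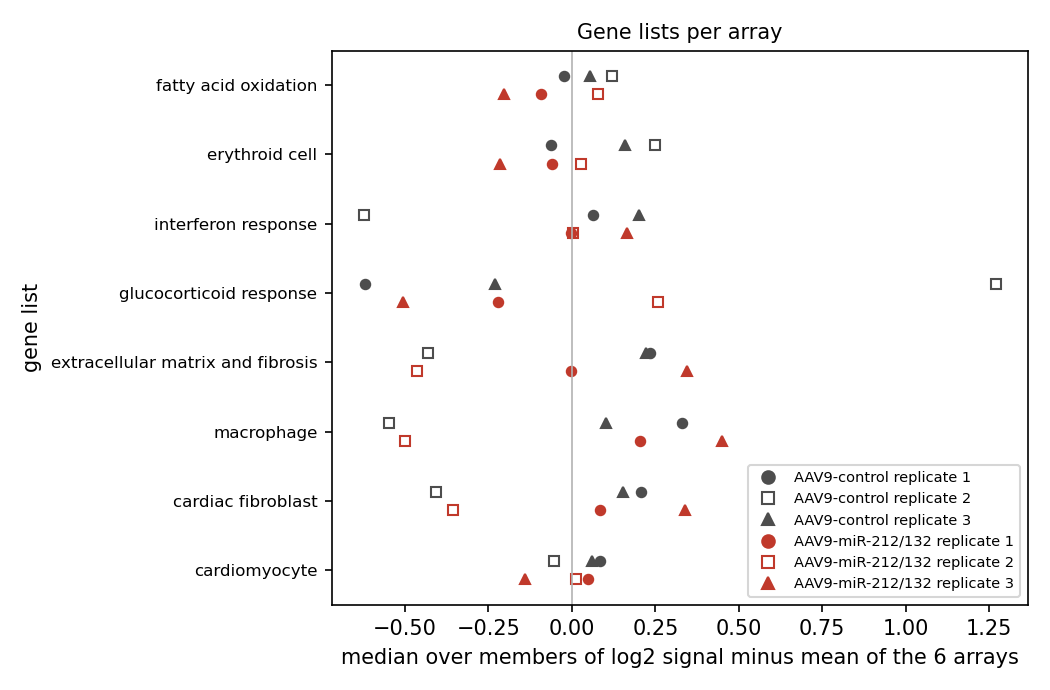
Median over the members of 8 gene lists of each array's log2 signal minus the mean of the 6 arrays, 1 point per array. The glucocorticoid list lies highest on control replicate 2, and the matrix, macrophage and fibroblast lists lie lowest on replicate 2 of both groups.

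The samples differed more between replicates than between groups. The first principal component held 55.4% of the variance and the second 22.6%, and on the first control replicate 2 scored 51.0 and microRNA replicate 2 scored 18.7, with the other arrays between -24.0 and -11.2. In control replicate 2, 1053 genes lay over 2-fold from the mean of the other controls, against 355 and 138 in control replicates 1 and 3, and in microRNA replicate 2 it was 416. Glucocorticoid response genes had a median 1.59 log2 units above the other controls there, and 0.70 above its group mates in microRNA replicate 2. Chosen after their values were seen, the co-chaperone Fkbp5 was 3.32 and 2.41 higher in these arrays, and the transcription factors Zbtb16 and Hif3a 3.05 and 1.07, and 2.84 and 1.19. Extracellular matrix genes lay at -0.80 and -0.61 and macrophage genes at -0.73 and -0.91 on the same arrays, for example Col1a1 at -1.76 and -1.78, Col3a1 at -2.50 and -2.81 and the macrophage receptor Cx3cr1 at -3.81 and -1.48. Interferon response genes lay at -0.76 in control replicate 2 and -0.02 in microRNA replicate 2. Without replicate 2 of both groups, an alternative chosen after seeing the data, 0 genes and 7 lists were called, fatty acid oxidation (median -0.16, adjusted p = 1.94e-08) and erythroid genes (-0.20, adjusted p = 0.00112) among them and the interferon and glucocorticoid lists not, with adjusted p of 0.507 and 0.948. Oxidative phosphorylation (-0.10, adjusted p = 0.0011) and cardiomyocyte genes (-0.14, adjusted p = 0.00476) were called lower in the same fit, and without control replicate 2 alone as well (adjusted p = 0.014 and 0.0156). None of these calls held with an estimated correlation (adjusted p = 0.729 with an estimated correlation for each of the 4 lists without both replicates, and 0.812 without control replicate 2) or with fry. The lower oxidative phosphorylation and cardiomyocyte values came mostly from microRNA replicate 3. Relative to the mean of all arrays, its list medians were -0.141 and -0.142, against 0.0537 and 0.0466 on microRNA replicate 1. They were 0.0418 and 0.083 on control replicate 1, and 0.0728 and 0.0601 on control replicate 3.

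**Figure D3:**
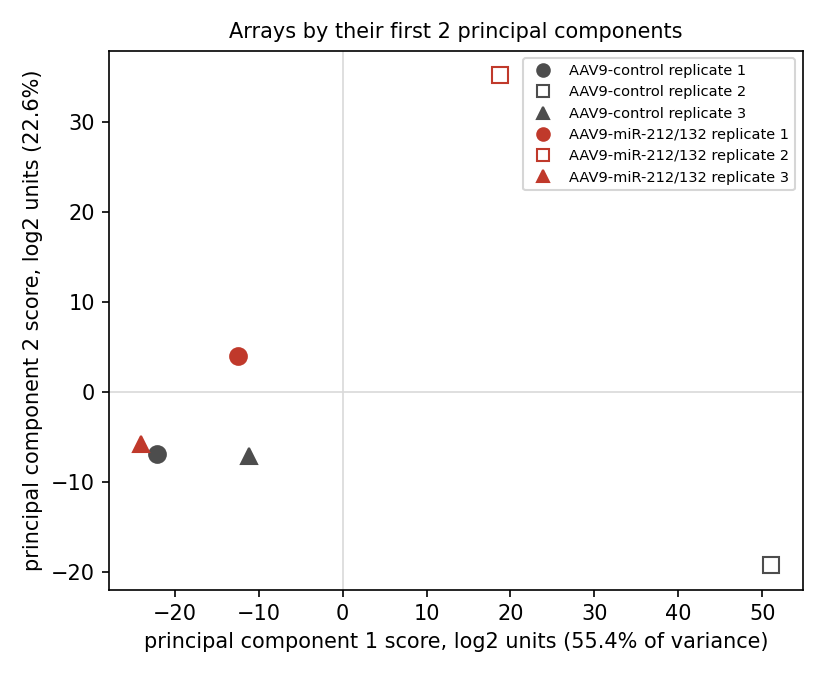
Scores of the 6 arrays on the first 2 principal components of the log2 signals of the tested genes, with the share of variance on each axis. Replicate 2 of both groups lies apart from the other 4 arrays, at 51.0 and 18.7 on the first component.

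In the authors' deposited table, 111 of 245 probes were higher and 134 lower in microRNA samples, and the groups were apart in all 245. The smallest ratio between the group means of its values was 1.25-fold, so its probes had been selected on these samples and their directions are not independent evidence. Across the 193 probes that followed their scanner signal, the log2 differences correlated at 0.973 with those from the scanner signals, across genes, which are not independent replicates. Of those 193 probes, 85 had an unadjusted limma p under 0.05 when every probe was tested. Over all its 245 probes, the authors' deposited table held the probes of 3 of the 12 genes named as higher and 4 of the 12 named as lower. The lower ones among the 193 were Arntl, Btnl9 and Itgb3, with mean log2 differences of -0.78, -0.70 and -0.65 there. The remaining lower one did not follow its named probe. The erythroid gene Car2 was in the table as well, at -0.34. It held 0 probes of Fitm2.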

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

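The cause of a change was not tested unless a sentence gives it. The count of changed genes stayed at 0 in 19 of 21 alternatives. It was 507 with array weights, a fit that rests mostly on control replicate 3 and microRNA replicate 1. It was 245 from the authors' deposited table alone, whose 245 probes had been selected on these samples. The smallest adjusted p with an array left out was 0.0662. At an unadjusted p under 0.05, the count of 515 became 897 without the filter on dim probes, where more genes were tested, 5221 with array weights, 852 with the replicate block, 878 with the slide block and 793 without control replicate 1. The called lists numbered 4, and 7 with quantile normalization, 7 without replicate 2 of both groups, 0 with an estimated correlation, 0 with fry and from 3 to 10 with an array left out. The replicate block changed the call of no list beyond the lipid droplet and inflammatory lists, nor of any gene. With an estimated correlation and with fry the medians stay as they are, -0.12 for fatty acid oxidation, -0.21 for erythroid, -0.29 for glucocorticoid and 0.17 for interferon genes and the calls end. With the slide block, which leaves out the lone array of slide 3, the medians were -0.0198, -0.15, 0.0033 and 0.0923 in that order. With an array left out they ran from -0.17 to -0.0670, from -0.31 to -0.14, from -0.63 to 0.25 and from -0.0400 to 0.41. Array weights gave 0.0403 for glucocorticoid and -0.15 for interferon genes, the fit without replicate 2 of both groups gave 0.0262 and -0.00301, and without the filter the glucocorticoid call ended at -0.29. The cell cycle list was called higher without replicate 2 of both groups, at 0.0700, and the macrophage list lower with the slide block, at -0.19, each against its main direction and not with an estimated correlation (adjusted p = 0.729 and 0.945). Of 31 lists not called, 12 were called under at least 1 alternative, in 42 of 651 fits. Of 48 named genes, 8 changed sign under at least 1 of 19 alternatives. The seed-site and vector microRNA alternatives were not run. Genes below background set the limit on dim signals, since 63.0% to 67.3% of probes were well above background.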

Other observations

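The tests of the slide, of the fibroblast share, of other probes, of the fatty acid oxidation list and the estimated correlation and fry beside other fits were chosen after the results were seen, and the test of array noise and the splits of the arrays before.

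Within the slides that held both groups, extracellular matrix genes had lower medians in microRNA samples, -0.25 on slide 1 and -0.43 on slide 2, and cardiac fibroblast markers moved with them, at -0.14 and -0.22. Slide 1 held 1 array per group. Relative to the mean of the 6 arrays, the matrix median was -0.464 on microRNA replicate 2, -0.431 on control replicate 2 and 0.223 on control replicate 3. The fibroblast medians were -0.355, -0.408 and 0.152 in that order. The slide 2 differences, taken against the mean of both controls, thus came mostly from control replicate 3. MicroRNA replicate 3, which the slide block leaves out, had the highest matrix median, 0.346. With slide as a block camera called the matrix list lower (adjusted p = 7.08e-06) but not the fibroblast list (0.0593), while the fit without a block (median -0.01, adjusted p = 0.376) and the replicate block (0.37) did not call the matrix list, nor did an estimated correlation or fry under the slide block (0.945 and 0.984). The matrix list was also called lower without control replicate 2 (-0.29, adjusted p = 7.63e-05), without microRNA replicate 3 (-0.25, 0.000383) and with array weights (-0.20, 0.001), and in none of these with an estimated correlation (0.812, 0.939 and 0.869), so its value leans on which arrays are compared. The slide block also called the macrophage (adjusted p = 0.0458) and cell cycle lists (0.00546) lower, but not with an estimated correlation (0.945 each). The macrophage list was called higher without microRNA replicate 2 (0.36, adjusted p = 0.00101) and without replicate 2 of both groups (0.10, 0.0471), and the cell cycle list higher in the latter fit (0.0700, 0.0366), again not with an estimated correlation (macrophage 0.835 and 0.747, cell cycle 0.729).

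The clock list was not called, with 11 of 18 members higher, 7 lower, a median of 0.06 and an adjusted p of 0.923, and 0 members passed over the list alone. Of its genes, picked after their values were seen, Arntl and Npas2, which encode partner activators, differed by -0.77 ± 0.18 and -0.40 ± 0.17, with no overlap of the groups for either, though Npas2 was above background on only 1 of the 3 microRNA arrays, while Dbp, an output gene of the clock, differed by 0.09 ± 0.26. No time of day is given in the sources used here.

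Control replicate 2 stood apart from the other controls. Noise of single probes on this array is argued against, since of 155 genes over 2-fold apart that had another measured probe, 92.9% moved the same way on that probe. Both probes read the same labelled RNA, so a fault in preparing that RNA would move them alike and is not excluded. A slide effect as the whole cause is argued against by control replicate 3 on the same slide, where glucocorticoid genes lay 0.132 above the arrays of other slides, against 1.74 for control replicate 2 and 0.655 for microRNA replicate 2, the third array of that slide. A lower share of fibroblasts as the whole cause is argued against by 5 of the 12 fibroblast markers, among them Dcn at 0.19 and Pdgfra at -0.16, while Col1a1 lay at -1.76. Among what stays open are the preparation of the RNA, the share of other cell types in the sample, and a state of the animals or their handling. Replicate 2 of both groups could share such a state. None of these was tested, since no group in the labels sets these samples apart.

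The 12 genes named as higher include several with little known role in heart muscle, and 8 of them had their lowest microRNA signal on the same array, replicate 3. These genes were selected on the same values and the share over all genes was not computed, so that count does not bear on a cause. A hypothesis is that some probes of the 12 genes bind another transcript, possibly one made from the vector. Of the 84 genes at least 1.5-fold higher without overlap, 8 had another measured probe, and those differed by a median of 0.182 where the probes used differed by 0.87. In 7 of these 8 the other probes moved in the same direction. For the 8 such genes among the 50 lower ones the medians were -0.369 and -0.715, with 6 in the same direction. With 8 genes each and a wide spread this leaves the hypothesis open, and chance selection of the probe used would lower the other probes too.

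The lower fatty acid oxidation list may reflect the state of control replicate 2, whose Pdk4 signal was 2.58 above the other controls, but without that array the list kept its call by camera with the preset correlation at a median of -0.092, though not with an estimated correlation (adjusted p = 0.812) or fry (0.955). Its median with slide as a block was -0.0198. Slide 3 held microRNA replicate 3 alone, so a slide effect and a feature of that sample cannot be told apart.

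The 6 arrays form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 called genes and the highest other split gave 1. Any split gives at least 0, so the count of 10 of 10 splits with as many says nothing about chance. At an unadjusted p under 0.05 the real split gave 515 genes and the highest other 2465, and 6 of the splits gave as many, which points to a structure of the samples. For the lists the real split gave 4 and the highest other 17, and 9 of the splits gave as many. The real split and 3 others part all 3 same-numbered pairs. Among those 3 the highest values were 0 genes called and 403 genes at the unadjusted threshold. They called 7, 8 and 6 lists, each more than the 4 of the real split. The splits with 2465 genes and with 17 lists put both replicate 2 arrays on 1 side.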
